A study of Homo sapiens with 4 samples.

How the data were processed

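The series held 4 libraries of MRC-5 cells, a line of human fetal lung fibroblasts. Cells at about 50% confluence received TCBQ (tetrachlorobenzoquinone, a redox-active quinone) at 20 µM or the solvent DMSO for 24 h. For each treatment 1 library was made from DNA carrying 5-hydroxymethylcytosine (5hmC), an oxidised form of methylated cytosine, and 1 from poly(A) RNA. Per the labels' protocols, DNA was extracted with 0.1 mM DFO, sheared to about 300 bp and enriched for 5hmC by chemical capture, and 10 ng of captured DNA went into each single-end library. The RNA libraries were made from 1 µg of total RNA. Samples were grouped by their titles. With 1 library per group no difference had a replicate check, and no p-value of a treatment effect was computed.

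Reads were aligned to hg19 with BWA (0.5.8 and 0.5.9-r16 are both named, without a role for each) and peaks were called with MACS 1.4.2, per the submitters' processing notes. Per the file headers, peaks were called in each library by itself with no control file, with a p cutoff of 1e-05 and at most 1 tag kept per position. The deposited peak lists give for each peak a count of tags, a score that is -10 times the log10 of the p-value, and a fold enrichment over the local background of the same library. Scores and fold enrichments are the authors' own values per peak, and were used to describe, rank or filter the peaks of each list. Where 1 threshold was applied to both lists, the numbers of peaks past it also depend on the enrichment of each library. Without an input or control library, regions that collect tags in any library are also called. After the authors' removal of repeated positions 20357543 of 35880543 tags were left in the TCBQ library and 19757784 of 36394594 in the DMSO library, a ratio of 1.03.

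The authors' deposited table of expression lists a symbol, an Ensembl identifier, a chromosome, a log2 ratio of the first library over the second, a normalized log2 ratio, a z-score and p-values for each gene. The normalized log2 ratio is the raw one plus 0.0382 for every gene, which was checked on the values. The aligner settings, annotation, gene counting, strand and differential test behind it are not given in the sources used here. Neither the header nor the labels name the treatment of the first or the second library, and it was not inferred from the values, so every expression ratio below is given as first over second and carries no direction of a TCBQ effect. The 2 columns of values per library were not tied to a treatment by a name and were not used. All listed genes had a p-value below 0.001 (the highest was 0.000999), so a gene that is not listed cannot be called unchanged. Of 10484 lines, 16 repeated a gene, which left 10468 genes, and 97.4% of their identifiers were found in the gene name table used here. Another 13 symbols had been turned into dates and were matched to no list.

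Shared peaks overlapped by at least 1 bp, and the overlap was set against 100 circular shifts of a list within each chromosome. Ratios of peak numbers carry exact 95% binomial intervals, and shares of peaks that overlap the other library carry 95% Wilson intervals. Other percentages with an interval carry exact binomial ones. These intervals cover counting error only and treat peaks or genes as independent. Intervals of a difference of medians or of correlations are 95% bootstrap percentiles. For expression a standard error was taken as the normalized log2 ratio divided by its z-score, and genes with a value of at most 0.2 were kept. This filter took the place of a minimum of 1 on the expression values, which had been fixed before the data were examined, and it was chosen after the data were seen, when limits of 0.1, 0.2 and none had been looked at. It left 9103 genes with a median standard error of 0.0542 on the log2 scale. That error also covers counting alone.

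Before the data were examined, 28 gene lists were fixed (23 for pathways and 5 for cell types). The median log2 ratio of each list with at least 3 genes kept was placed among 10000 random lists of the same size, matched on the standard error in 20 bins, in place of mean expression. A list was called high or low beyond the 97.5 or 2.5 percentile, where chance puts 5% of lists. Percentiles describe these libraries and test no treatment. Genes were named by a rule fixed in advance: the 12 largest ratios in each direction, up to 4 members per list, the TET and DNMT enzymes and TDG, and the 5 unshared peaks with the highest score in each library. Some genes this rule names are not reported here. Genes of chromosome 3 filled 1 of these groups, so the 12 largest outside it were added after the data were seen. Simulated lists of 15 genes drawn from the 9103 kept were called in 3% of 200 draws without a shift and in 100% with a log2 shift of 1.5. That shift is larger than most list medians given below, and smaller shifts were not simulated. The draws came from the same genes as the random lists, so lists of co-regulated genes were not checked. An overlap of 52.1% planted in shifted peak lists was recovered as 52.1%.

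Alternatives were a score of at least 100, a fold enrichment of at least 10, the same number of top-scoring peaks, merging peaks closer than 500 bp, chromosomes 1 to 22 and X alone, reciprocal overlap of 50%, a distance of 1000 bp, no expression filter, a standard error of at most 0.1, centring on the median, a size rule of 1.5-fold and leaving out chromosome 3. Gene positions in hg19 were not used here, so peaks were placed by chromosome and coordinate alone, and the planned link between peaks and the expression of the genes that hold them was not analysed here. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.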

Results

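The data comprised 5hmC maps and transcriptomes of MRC-5 fibroblasts after 24 h with 20 µM TCBQ or with DMSO, with 1 library per treatment and assay. The series asked whether a redox-active quinone changes the level and placement of 5hmC in cells, and how gene expression differs alongside. About equal numbers of tags remained in both 5hmC libraries (20357543 with TCBQ and 19757784 with DMSO), while the depth of the RNA libraries is unknown from the values used. No value below has a replicate.

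The first comparison was the amount of 5hmC enrichment with TCBQ against DMSO. In the TCBQ library 78064 regions were called as 5hmC peaks, and in the DMSO library 73474, a ratio of 1.06 (95% interval 1.05 to 1.07). These peaks covered 80.6 Mb with TCBQ and 74.1 Mb with DMSO, with median lengths of 819 bp and 786 bp. They held 20.4% of all tags with TCBQ and 15.2% with DMSO, and the mean tag density inside them was 2.53 and 2.05 tags per kb per 1000000 tags of the library. Strongly enriched regions differed more: 29470 TCBQ peaks (37.8%) and 18258 DMSO peaks (24.8%) reached the authors' score of 100, a ratio of 1.61 (1.58 to 1.64). A fold enrichment of 10 was reached by 20925 and 11594 peaks, a ratio of 1.80 (1.76 to 1.85). The ratio of peak numbers thus moved by over 1.5 times with the threshold of the peak list. Because scores grow with the enrichment of a whole library and no control library entered the calls, these ratios describe the pair of libraries.

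The same places were then compared between treatments. Of the TCBQ peaks 36984 (47.4%, 47.0 to 47.7) overlapped a DMSO peak, and of the DMSO peaks 37035 (50.4%, 50.0 to 50.8) overlapped a TCBQ peak. Shifted lists gave 5.35% and 5.66% on average, so the observed overlap was 8.85 and 8.90 times as high. High-scoring regions were shared most. In the lowest 10% of the scores 25.6% of TCBQ peaks and 26.1% of DMSO peaks were shared, and in the highest 10% 89.6% and 91.9%. Within 35894 regions that held 1 peak of each library, tags scaled to the library total were higher with TCBQ in 68.7%, with a median log2 ratio of 0.33 (quartiles -0.14 and 0.76), which is 1.26-fold. Peak lengths in these regions differed as well (medians 946 bp and 895 bp), and per base the median was 1.12-fold higher with TCBQ. The share of all tags that lay in peaks was itself 1.34 times as high with TCBQ. Both libraries were made from 10 ng of captured DNA, so these ratios do not give the amount of 5hmC per cell. A stronger capture in the TCBQ library cannot be told apart from more 5hmC at these places. Peaks found in 1 library alone were the weaker ones, with median scores of 69.1 against 112 for shared TCBQ peaks and 62.5 against 87.8 for shared DMSO peaks.

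**Figure D1:**
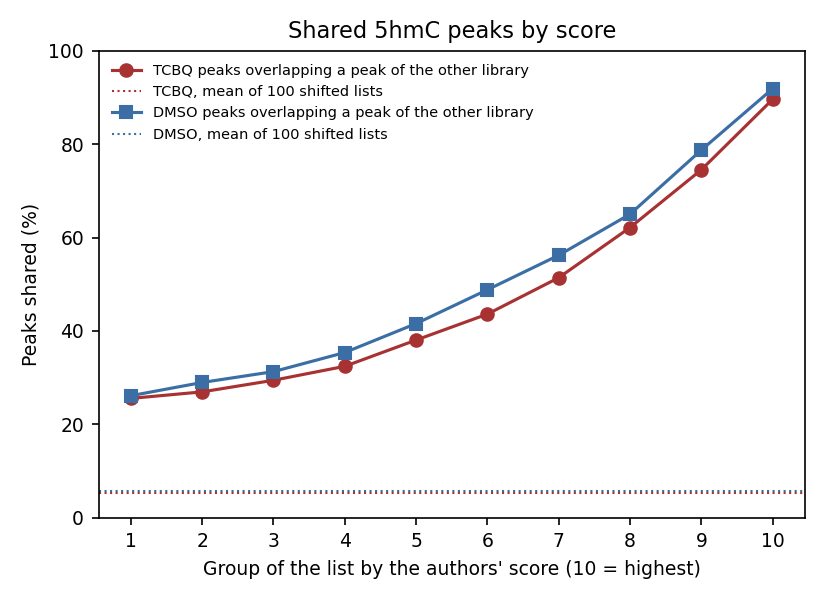
Percentage of 5hmC peaks that overlap a peak of the other library (vertical axis) in 10 equal groups of each list ranked on the authors' score (horizontal axis, 10 highest), for TCBQ (circles) and DMSO (squares), 1 library each; dotted lines are means of 100 shifted lists. Sharing goes from 25.6% to 89.6% of TCBQ peaks and from 26.1% to 91.9% of DMSO peaks, above the shifted means of 5.35% and 5.66%.

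The strongest unshared regions lay at the following hg19 positions. With TCBQ alone, the highest score was 1814, at chromosome 2, 92295722 to 92298772, with 1134 tags over 3051 bp. Next came chromosome 9, 33623867 to 33625733 (score 1479), and chromosome 9, 135894412 to 135896883 (score 1477). The other TCBQ regions named were chromosome 7, 22549892 to 22551680 (score 1450.1), and chromosome 7, 132719292 to 132721047 (score 1407). With DMSO alone, the highest score was 396, at chromosome 5, 17517284 to 17519617, with 395 tags. It was followed by chromosome 4, 49280558 to 49284168 (score 313), chromosome 9, 130297659 to 130299021 (score 312), chromosome 6, 71466393 to 71468052 (score 306), and chromosome X, 72229037 to 72231708 (score 293). Of 9875 TCBQ peaks with a score above 200, a threshold chosen after the data were seen, 1201 (12.2%) were unshared. With no control library, regions that collect tags for reasons other than 5hmC cannot be told apart from the others. Whether these regions lie in genes was not analysed here.

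By chromosome, TCBQ peaks were most abundant relative to DMSO on chromosome 22, with 1207 against 767 (ratio 1.57, 1.44 to 1.72), and on chromosome 19, with 1999 against 1385 (1.44, 1.35 to 1.55). Chromosomes 16, 15 and 10 followed with ratios of 1.21, 1.21 and 1.19. Chromosome 8 had fewer TCBQ peaks, 4914 against 5522 (0.89, 0.856 to 0.925), as did chromosomes 9 (0.934) and 5 (0.953). Of 24 chromosomes 15 had an interval above 1, 3 had one below 1, and for 6 it held 1. With 36737 top-scoring peaks from each list, an alternative added after the data were seen, 8 chromosomes had an interval above 1, 7 had one below 1 (3, 5, 8, 9, 11, X and Y), and for 9 it held 1. The ratios were then 1.34 (1.18 to 1.52) on chromosome 22, 1.41 (1.28 to 1.56) on chromosome 19 and 0.792 (0.748 to 0.839) on chromosome 8. The ratio on chromosome 8 turned to 1.35 among peaks with a score of at least 100, a set in which TCBQ had 1.61 times as many peaks genome-wide.

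**Figure D2:**
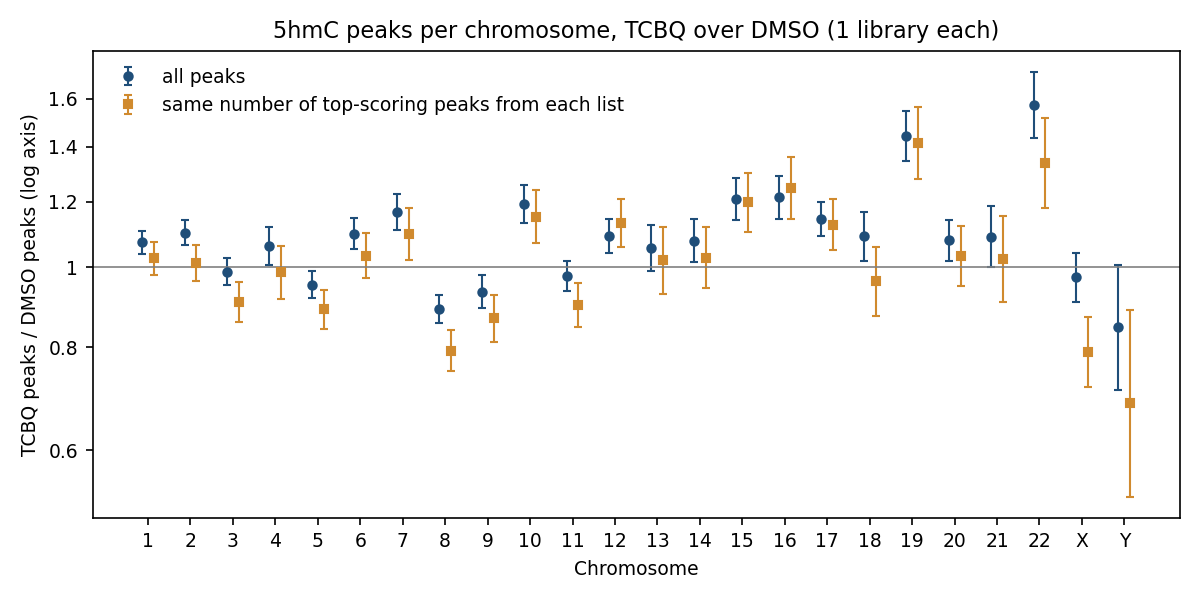
Number of TCBQ peaks over number of DMSO peaks on each chromosome (logarithmic vertical axis) for all peaks (circles) and for 36737 top-scoring peaks from each list (squares), 1 library each; bars are exact 95% intervals that cover counting error only. Chromosomes 19 and 22 lie highest, at 1.44 and 1.57 for all peaks, and chromosome 8 lies at 0.89.

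The last comparison was between the RNA libraries, whose treatments the authors' deposited table does not name. Of the 9103 genes kept from the authors' deposited table, 4853 were higher in the first library and 4250 in the second, and at least 2-fold differences numbered 746 and 1032. The largest ratios toward the first library included those of FOSB and FOS, subunits of the AP-1 transcription factor, at log2 ratios of 7.84 and 7.27 in the authors' deposited table. HSPA6, an inducible heat shock protein, stood at 7.45 there, and the collagenase MMP1, the chemokine IL8 and the stromelysin MMP3 at 6.42, 6.03 and 4.80 (all in the authors' deposited table). OSGIN1, an oxidative stress gene, RND1, a small GTPase, NR4A2, an orphan nuclear receptor, and HEY1, a Notch target, had ratios of 4.70, 4.23, 3.98 and 3.81 in the authors' deposited table. GADD45B, a growth arrest gene, and ZFAND2A, a zinc finger gene induced by arsenite, complete the 12 largest with 3.77 and 3.64 in the authors' deposited table.

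All 12 of the largest ratios toward the second library belonged to chromosome 3, from -8.81 for GPX1, a glutathione peroxidase, to -6.06 for MANF, a protein of the endoplasmic reticulum, in the authors' deposited table. The others were TRIM59, RP11-553A10.1, DAG1 (dystroglycan), the ribosomal proteins RPL29 and RPL32, KIAA1143, PCNP, IQCJ-SCHIP1, ZNF654 and FGD5-AS1. Of 968 genes of chromosome 3 in the authors' deposited table, 964 were higher in the second library, 902 of them at least 2-fold, with a median log2 ratio of -3.20. The 562 of them under the standard error limit had a median of -2.17 in the authors' deposited table. Ratios below -5 occurred for 301 genes of chromosome 3 and for 0 genes of any other chromosome in the authors' deposited table. This chromosome held 500 of the 1032 genes at least 2-fold higher in the second library in the authors' deposited table. Without it the counts were 746 and 532. Outside it, chosen after the data were seen, the largest ratios toward the second library in the authors' deposited table were those of CENPE (-3.04), FAM198B (-2.93), ANKRD26 (-2.63), KIF20B (-2.49), UACA (-2.46) and AC004383.4 (-2.45). SYNE2, CENPF, ARHGAP28, LRRC7, CEP290 and COL11A1 followed, from -2.29 to -2.12 in the authors' deposited table. Of these 12, CENPE, CENPF and KIF20B act in mitosis. Whether the ratios went with transcript length or RNA quality was not tested. The median of all kept genes in the authors' deposited table was 0.20, and centring on it gave 419 and 1444 genes at least 2-fold higher in the first and the second library. That median covers only genes past the authors' threshold, with chromosome 3 among them. Centring therefore serves as an alternative and not as a correction.

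**Figure D3:**
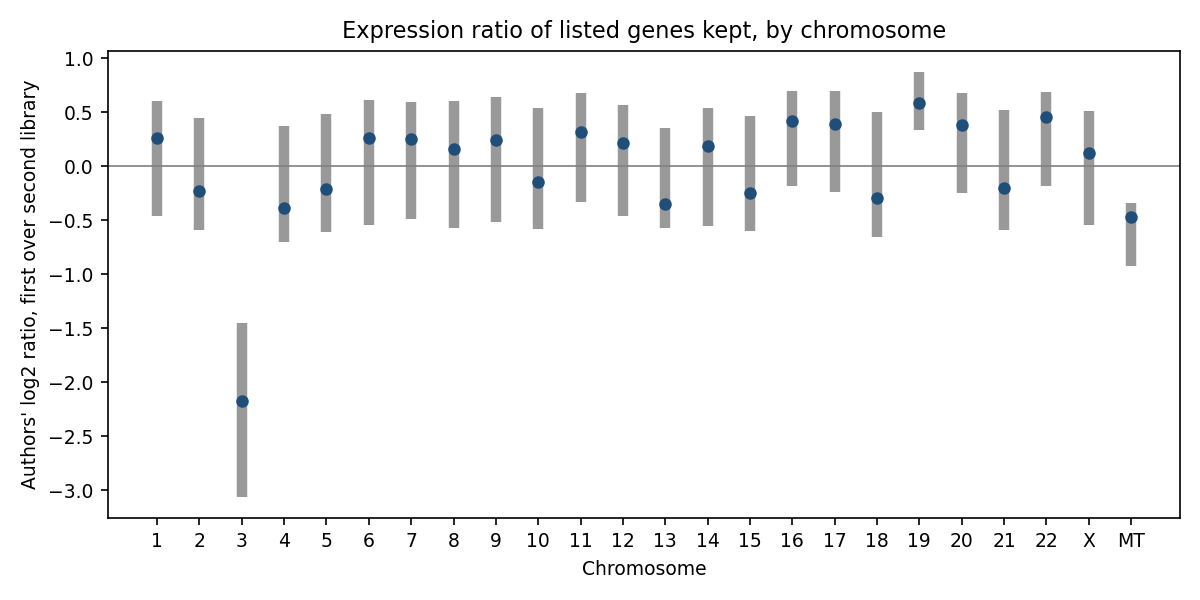
Median (points) and quartiles (bars) of the log2 ratio, first over second library, among genes kept from the authors' deposited table, by chromosome (horizontal axis; MT is the mitochondrial genome), 1 library each and treatments not named. Chromosome 3 lies at -2.17, chromosome 19 at 0.58 and the mitochondrial genes at -0.47.

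Among the gene lists, 14 stood outside the percentile limits, 8 high and 6 low. The random lists were not matched on chromosome, gene density, transcript length or GC content. Medians of kept genes differed by chromosome in the authors' deposited table, for example 0.58 on chromosome 19 and -0.35 on chromosome 13. The percentiles do not allow for such differences. Immediate early genes, transcribed within minutes of a stimulus, had a median log2 ratio of 2.01 in the authors' deposited table, with 16 of 17 members higher in the first library (percentile 100). Beside FOS and FOSB, JUNB stood at 3.57 and EGR1 at 3.21 in the authors' deposited table. Inflammatory cytokines and NF-kB targets had a median of 2.15 with all 11 kept members higher in the first library in the authors' deposited table (percentile 100), among them RELB at 2.81. Under a standard error of at most 0.1, chosen after the data were seen, 4 members were left and the median was 0.51 in the authors' deposited table (percentile 86.6). Matrix proteases and inhibitors, which share MMP1 and MMP3 with that list, had 11 of 14 members higher in the first library and a median of 0.57 in the authors' deposited table (percentile 99.1), with PLAUR at 1.34 and ADAMTS1 at 1.26. Under the stricter limit their median was 0.40 in the authors' deposited table (percentile 90.3), and after centring on the median of all kept genes it was 0.37, with 10 of 14 higher in the first library.

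NRF2 (NFE2L2) antioxidant response targets were higher in the first library in 25 of 27 cases, with a median log2 ratio of 0.98 in the authors' deposited table (percentile 100). OSGIN1 led them, followed by HMOX1, heme oxygenase 1, at 3.57, the autophagy receptor SQSTM1 at 2.31 and TRIM16L at 2.15 in the authors' deposited table. The exceptions were ABCC1 and TKT, the latter on chromosome 3. Targets of ATF4 and the unfolded protein response had 17 of 19 members higher in the first library and a median of 1.25 in the authors' deposited table (percentile 100). They included PPP1R15A at 3.10, DDIT3 (CHOP) at 2.54, ATF3 at 2.44 and SESN2 at 2.40 in the authors' deposited table. All 22 proteasome subunits were higher in the first library, with a median of 0.80 in the authors' deposited table (percentile 100), and PSMC1, PSMC4, PSMB4 and PSMB3 stood at 1.76, 1.35, 1.11 and 1.07. Of 24 ribosomal proteins 23 were higher in the first library with a median of 0.57 in the authors' deposited table (percentile 99.96). RPL18 and RPS9 had 1.04 and 0.99, and the exception RPL15, on chromosome 3, had -5.35 in the authors' deposited table. After centring 22 of the 24 were higher in the first library, with a median of 0.37 in the authors' deposited table. Replication-dependent histones had 5 kept members, all higher in the first library, with a median of 1.34 in the authors' deposited table (percentile 99.99). With no filter on the standard error all 11 listed members were higher in the first library, with a median of 2.20 in the authors' deposited table (percentile 100). HIST1H2BK, HIST1H1C, HIST2H2BE and HIST1H2AC stood at 2.20, 1.81, 1.34 and 1.30 in the authors' deposited table. The libraries were of poly(A) RNA, so the histone values cover polyadenylated transcripts alone. Histone, ribosomal protein and ferritin genes have close copies or pseudogenes that can share reads, so their single values are uncertain.

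Extracellular matrix genes of fibroblasts were lower in the first library in 14 of 16 cases, with a median of -0.72 in the authors' deposited table (percentile 0.010). COL3A1, FBN1 (fibrillin), COL5A2 and VCAN (versican) had -1.85, -1.68, -1.49 and -1.45 in the authors' deposited table. The exceptions were THBS1 and COL6A2. Fibroblast markers, of which 4 of 6 kept genes are also in the matrix list, had a median of -1.25 in the authors' deposited table (percentile 0.020) and 5 of 6 lower in the first library, with COL1A2 at -1.39, COL1A1 at -1.35 and PDGFRB at -1.14, the exception being VIM at 0.39. Cell cycle genes were lower in the first library in 22 of 30 cases with a median of -0.43 in the authors' deposited table (percentile 0.080). Besides CENPE and CENPF, TOP2A, a topoisomerase of dividing cells, had -1.50 and MCM2, a replication gene on chromosome 3, had -1.29 in the authors' deposited table. Of the 8 members higher in the first library, CDT1 had 1.12 and CDC20 had 0.38 there. All 18 kept genes of cholesterol and fatty acid synthesis were lower in the first library, with a median of -0.46 in the authors' deposited table (percentile 0.54), including SCD at -1.18, STARD4 at -0.94 and SC5DL at -0.76. Interferon response genes had 8 of 9 members lower in the first library and a median of -0.80 in the authors' deposited table (percentile 1.1). IFIT1 had -1.80, RSAD2 -0.95 and OAS3 -0.93, and the exception IRF7 had 1.12 in the authors' deposited table. AHR targets had a median of -0.88 over 5 genes in the authors' deposited table (percentile 1.31), with CYP1B1 at -1.71, AHRR at -0.88, NQO1 at 1.18 and TIPARP, on chromosome 3, at -2.97. Without chromosome 3 their median was -0.55 in the authors' deposited table (percentile 4.47), inside the limits.

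The list for writing, oxidising and removing 5-methylcytosine stayed within the percentile limits. It had 6 genes higher in the first library, 7 in the second, and a median of -0.16 in the authors' deposited table (percentile 29.0). Not all of them act on 5-methylcytosine directly, since GADD45A, GADD45B, UHRF1, XRCC1, IDH1, IDH2 and OGDH were among the kept members. Without chromosome 3 there were 6 on each side with a median of -0.02, and centring gave 4 and 9 with a median of -0.36, in the authors' deposited table. TET1 and TET2, dioxygenases that form 5hmC, had -1.31 and -0.82 in the authors' deposited table, while TET3 had 0.48. The maintenance methyltransferase DNMT1 had 0.11 in the authors' deposited table, which turned negative when the median of 0.20 was subtracted. TDG, DNMT3A and DNMT3B were not among the listed genes, so no value can be given. GADD45B and GADD45A, at 3.77 and 2.40 in the authors' deposited table, and MBD4, on chromosome 3, at -1.79, had the largest ratios of the group.

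Other lists within the limits held members on both sides. Targets of p53 had 9 of 14 members higher in the first library in the authors' deposited table (median 0.44, percentile 87.6), with GDF15 at 3.61, CDKN1A (p21) at 2.56 and ZMAT3, on chromosome 3, at -3.79. Hypoxia targets had a median of 0.51 in the authors' deposited table (percentile 96.7), led by NDRG1 at 2.15, VEGFA at 1.94 and PFKFB3 at 1.43, with PFKFB4, on chromosome 3, at -1.71. Apoptosis regulators had a median of 0.48 in the authors' deposited table (percentile 94.3), with PMAIP1 at 1.75, BCL2L11 at 1.70, BAK1 at 1.07 and BID at 0.69. Heat shock genes had a median of 0.23 in the authors' deposited table (percentile 70.0), and HSPB8, BAG3 and DNAJB1 stood at 2.09, 1.15 and 1.13. HSPA1B, at 2.41 in the authors' deposited table, has a nearly identical copy and is uncertain. Metallothioneins and zinc genes had a median of 0.62 in the authors' deposited table (percentile 90.8), with MT1X at 0.87, MTF1 at 0.69, MT2A at 0.62 and MT1F at -0.44. Oxidative phosphorylation had a median of 0.32 in the authors' deposited table (percentile 81.1), with NDUFS3 at 0.53, NDUFA4 at 0.50 and NDUFB5, on chromosome 3, at -2.15. Iron handling genes had a median of -0.31 in the authors' deposited table (percentile 11.7), with the ferritin chains FTL and FTH1 at 1.68 and 1.41 and the transferrin receptor TFRC, on chromosome 3, at -2.47. DNA repair genes had a median of -0.36 in the authors' deposited table (percentile 5.73), with BRCA2 at -1.81, BRCA1 at -0.95, and OGG1 and FANCD2, both on chromosome 3, at -2.40 and -1.62. TGF-beta and contractile genes had 7 of 14 members on each side and a median of 0.05 in the authors' deposited table (percentile 44.9), with ID2 at 3.56, CTGF at 1.12, ITGA11 at -1.25 and SKIL, on chromosome 3, at -3.18. That median was -0.16 after centring, -0.11 with no filter and 0.21 without chromosome 3 in the authors' deposited table. Centring also moved other medians of these lists by over 1.5 times in the authors' deposited table. They became 0.24 for p53 targets, 0.31 for hypoxia targets, 0.27 for apoptosis regulators, 0.12 for oxidative phosphorylation, -0.51 for iron handling and -0.56 for DNA repair. The median of heat shock genes was moved as well, to 0.02 in the authors' deposited table. There 9 of 15 members were then higher in the first library in place of 11.

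Markers of other cell types were too few to place among the genes kept. Kept were 2 epithelial genes (KRT18 at 0.70 and CDH1 at -1.58), 0 endothelial genes, 1 leukocyte gene (CD68 at 1.41) and 1 smooth muscle gene (SMTN at 0.70) from the authors' deposited table. With no filter, 4 leukocyte genes, all higher in the first library as the inflammatory genes were, had a median of 1.93 in the authors' deposited table (percentile 94.8): ITGAM at 2.78, CD14 at 2.19, CSF1R at 1.67 and CD68. Mitochondrially encoded genes were higher in the second library in 21 of 23 cases, with a median of -0.47 in the authors' deposited table. Since only genes past the authors' own threshold are listed and each library is single, counts and medians from the authors' deposited table describe this pair of libraries.

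**Figure D4:**
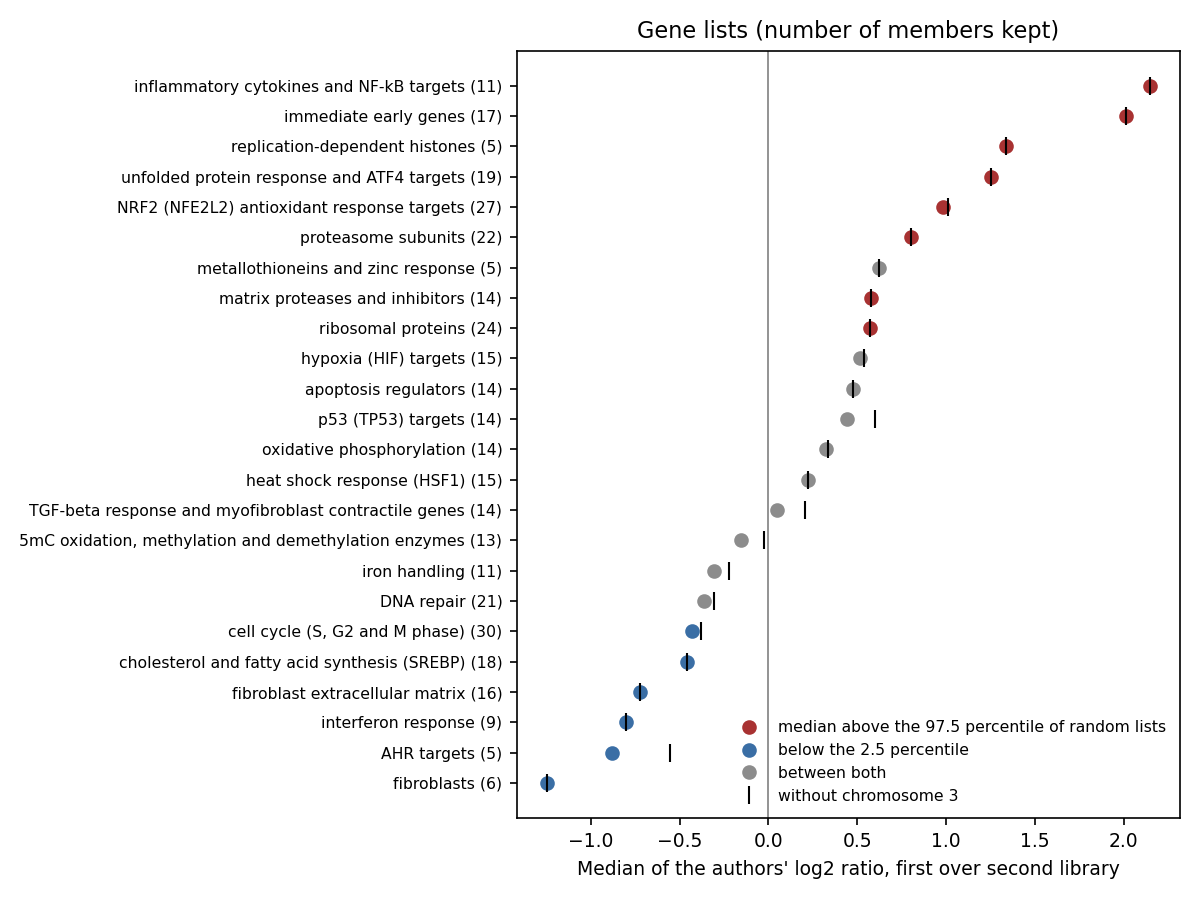
Median log2 ratio, first over second library, of each gene list with at least 3 genes kept from the authors' deposited table (horizontal axis; number of kept members in brackets), with colour giving its place among 10000 random lists and a vertical tick giving the median without chromosome 3. Inflammatory and immediate early genes lie highest, at 2.15 and 2.01, and fibroblast markers lowest, at -1.25.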

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

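Leaving out chromosome 3, the standard error limit of 0.1 and the top-scoring peaks by chromosome were chosen after the data were seen. With a score of at least 100, and with a fold enrichment of at least 10, the TCBQ over DMSO ratio was 1.61 and 1.80 for peak number, 1.47 and 1.96 for covered length, 2.07 and 2.26 for chromosome 22, 2.40 and 2.71 for chromosome 19, 1.35 and 1.42 for chromosome 8 (from 0.89) and 1.19 and 1.80 for chromosome X (from 0.972). Shared TCBQ peaks were 38.3% and 35.0%, and shared DMSO peaks 61.7% and 63.2%. Why chromosomes 8 and X reversed was not tested beyond the genome-wide ratios in the same sets. Covered length was 1.09 times as large after merging peaks closer than 500 bp and on chromosomes 1 to 22 and X. Shared TCBQ peaks were 50.2% among the same number of top peaks, 47.8% after merging, 42.0% with a reciprocal overlap of 50% and 51.5% within 1000 bp; shared DMSO peaks were 44.6% and 54.1% under the last pair. With the same number of top peaks the ratio was 1.34 on chromosome 22 and 0.792 on chromosome 8, and chromosomes with an interval above and below 1 numbered 8 and 7 in place of 15 and 3. Genes at least 2-fold higher in the first and the second library numbered 1332 and 1678 with no filter, since more genes were counted, 2306 and 2224 with a size rule of 1.5-fold, and 419 in the first after centring. In the second they were 685 with a standard error of at most 0.1 and 532 without chromosome 3. Of the 14 lists outside the limits, all 14 kept their side with no filter and after centring (which cannot move a percentile), 12 with a standard error of at most 0.1, where 2 others (hypoxia targets and DNA repair) also passed, and 13 without chromosome 3. Of 96 alternative medians of single lists, 94 kept their sign, of which 16 differed from the main value by over 1.5 times, and the other 2, with no filter and after centring, were those of TGF-beta genes. Pseudocounts, a higher minimum value, the upper quartile scaling, placement by any overlap and every choice on genes with 5hmC peaks were not run, since the columns of values per library, which no name ties to a treatment, and gene positions in hg19 were not used here. No paired analysis was possible because each group held 1 library. The effect of depth was not tested.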

Other observations

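Tests on chromosome 3, on chromosome 19 and on strong unshared peaks were chosen after those results were seen, as were the windows; the bounds for chromosome 22, for gene-rich chromosomes and for the link between peaks and expression were set before the values they judge were computed. Chromosome 22 itself was chosen after its ratio over all peaks had been seen, and the bound for the link was dropped for a time and restored unchanged after the correlations behind it had been seen. Among 1588 windows of 1 Mb with at least 40 peaks in both libraries together, 56 had at least 2-fold more TCBQ peaks and 21 at least 2-fold more DMSO peaks. The largest ratios toward TCBQ were on chromosome 16 from 83000001 to 84000000 (33 against 7 peaks), on chromosome 22 from 31000001 to 32000000 (48 against 13) and on chromosome 19 from 11000001 to 12000000 (54 against 17), in hg19. Toward DMSO they were on chromosome 9 from 1000001 to 2000000 (16 against 47) and on chromosome 8 from 78000001 to 79000000 (13 against 37). Their counting intervals were 2.05 to 12.6, 1.97 to 7.43 and 1.81 to 5.84 toward TCBQ, and 0.18 to 0.611 and 0.171 to 0.676 toward DMSO, and they do not allow for the choice of extremes.

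Expression ratios also differed between chromosomes other than 3. Genes of chromosome 19 were higher in the first library in 85.6% of cases and those of chromosome 13 in 34.1%, in the authors' deposited table. Across 22 chromosomes (3 and Y left out) the median log2 ratio in the authors' deposited table went with the number of listed genes per Mb, with Pearson's r = 0.70 and a Spearman correlation of 0.88 (permutation p = 1e-05 each, the smallest that 100000 permutations can give; adjusted p = 3e-05 over 3 relations). Without chromosomes 17 and 19, which lie farthest out, r was 0.81. Chromosomes are not independent samples. Listed genes are those past the authors' p threshold in the same comparison. Their number per Mb therefore depends partly on the ratios themselves and is not a plain measure of gene density. Of 6 such relations looked at, the 3 given are those among peak ratio, expression ratio and listed genes.

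Genes of chromosome 3 were lower in the first RNA library, with 4 exceptions in the authors' deposited table, named after their values were seen: HES1 (4.40), RRP9 (0.86), IRAK2 (0.52) and ALAS1 (0.23). Loss of 1 of 2 copies of the chromosome would put ratios near -1, while 56.8% (52.6 to 60.9) of kept genes in the authors' deposited table lay below -2, which argues against it. Reads ending partway along the chromosome would spare a stretch of neighbours, but in 26 groups of 30 neighbouring genes (792 of 968 genes matched to their order in GRCh38) the highest median was -1.92. A candidate explanation that stays open is that most of its reads went missing when the first library was aligned or counted. Then pseudogenes elsewhere with parents on chromosome 3 may have taken up reads. Of these, 14 had a median 0.12 above that of 314 others (bootstrap interval 0.010 to 0.95, one-sided permutation p = 0.173), in the authors' deposited table. The interval and the permutation test point different ways, and neither decides it. The 5hmC libraries had 5236 peaks on chromosome 3 with TCBQ and 5302 with DMSO (ratio 0.988, 0.95 to 1.03). These counts argue against complete loss of the chromosome from the DNA of either treatment. Each peak was scored against the local background of the same library, so peak counts cannot decide on a partial loss. Over all chromosomes the ratio was 1.06. With the same number of top-scoring peaks it was 0.908 (0.858 to 0.960) on chromosome 3. Log2 ratios below -5 occurred for 301 of its 968 listed genes and for no gene of another chromosome. Such confinement argues against a treatment effect on separate genes. A treatment effect on transcripts of the whole chromosome was not tested and stays open.

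The peak ratio differed between chromosomes, and stronger enrichment with TCBQ might add peaks everywhere. With the same number of top peaks it should then fall under 1.1 on chromosome 22, and it was 1.34 (1.18 to 1.52), above that bound but not clear of the 1.2 that was set, before this ratio was computed, to exclude it. Chromosome 19 lay clear of it at 1.41 (1.28 to 1.56), but it was looked at afterwards, so it cannot settle the question. Under the bounds set for chromosome 22, enrichment strength alone was neither borne out nor excluded, and it stays open. Recovery of GC-rich DNA could differ between the libraries, for which chromosomes with more listed genes per Mb served as a stand-in. The Spearman correlation with listed genes per Mb was 0.37 (permutation p = 0.0882, adjusted p = 0.0882; r = 0.50, permutation p = 0.0363, adjusted p = 0.0544, and r = 0.23 without chromosomes 17 and 19), between the bounds of 0.2 and 0.5, so this and an effect of the treatment cannot be told apart.

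Among TCBQ peaks with a score above 200, 1201 overlapped no DMSO peak (other thresholds, 1 of them set by the DMSO list, were looked at too). A DMSO peak just outside their edges would account for them, but 7.16% (5.77 to 8.77) had one within 1000 bp. DNA derived from abundant transcripts in the TCBQ library is a candidate source, as it would favour gene-rich chromosomes. For these 1201 peaks the Spearman correlation with listed genes per Mb was 0.50, and for as many top DMSO-only peaks -0.056. The difference of 0.56 had a bootstrap interval over chromosomes from 0.038 to 0.988, which reaches below the 0.3 required. Such DNA and the treatment therefore cannot be told apart without gene positions.

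Chromosomes with a higher peak ratio did not clearly have higher expression ratios in the authors' deposited table (Spearman correlation 0.37, permutation p = 0.087, adjusted p = 0.0882; r = 0.35, permutation p = 0.11, adjusted p = 0.11, and r = -0.03 without chromosomes 19 and 22). With the listed genes per Mb partialled out the Spearman correlation was 0.11, under the bound of 0.3 set for a shared dependence on gene density. Listed genes per Mb only stand in for that density, and a relation this weak leaves little to account for.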
